A study of Mus musculus with 12 samples.

How the data were processed

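RNA from 5 sorted populations of DCs and their progenitors was measured on 12 Affymetrix whole-transcript arrays. Per the labels' protocols, cells came from 8 to 10 littermates with a GFP reporter at Zbtb46, bone marrow was released with mortar and pestle, and spleen was digested with collagenase B and DNase. RNA was amplified with the NuGEN Ovation Pico WTA system and labelled with biotin. CDPs were gated as lineage-negative, CD117 intermediate, CD135 and CD115 positive, CD11c and MHC class II negative. Pre-CD8 cells were CD117 intermediate, CD135 and CD11c positive, Siglec H negative and intermediate for MHC class II. Pre-CD4 cells were CD117 low, CD135, CD115 and CD11c positive and MHC class II negative. CD172a DCs were sorted as positive for CD11c, MHC class II and CD172a, and CD24 DCs as positive for CD11c and CD24, negative for CD172a and, in the label, negative for MHC class II.

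The table held 1 log2 expression value per probe set and array, as deposited by the authors, with replicates not pooled. The background correction, summarization and normalization are not given in the sources used here. Values ran from 0.84 to 13.09 and were used without further normalization because array means differed by little. Array medians (4.89 to 5.24) and interquartile ranges (2.10 to 2.86) differed more, so near-equal means do not show a common scale. By the plan, arrays not on a common scale were to be quantile-normalized. Whether that condition held was not settled, and quantile normalization was run as an alternative. No detection calls were used, so the background level is unknown and a low value need not be a detected transcript. Of the 35145 probe sets, 23525 had exactly 1 gene symbol in the platform annotation, 1810 had several and 9810 had none listed. No symbol needed updating against the gene table used here, which is of the mouse assembly GRCm38.p6. Probe sets with no or several symbols were left out of the gene tests. Of 22184 genes, 1082 had several probe sets, and the one with the highest mean over the 12 arrays was used. Of 485 genes in the fixed lists, 449 were measured; Clec9a, a gene of the fixed panel, was not analysed here because its probe set lists several symbols.

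Differences between groups were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes). All 12 arrays entered a single fit with a mean for each of the 5 groups, so that groups of 2 shared the estimate of spread (residual degrees of freedom 7, prior degrees of freedom 6.18). P-values are two-sided and Benjamini-Hochberg adjusted over the 22184 genes, with a threshold of 0.05. The comparisons were pre-CD8 and pre-CD4 against CDP, pre-CD8 against pre-CD4, CD24 DC against CD172a DC, and each mature population against the progenitor of its lineage. A further contrast tested whether the lineage difference differed between stages. No comparison held 3 arrays in each group, so splits of the samples were not counted. Gene lists were tested with camera at an inter-gene correlation of 0.01, adjusted over 26 lists and 7 contrasts, and again with the correlation estimated from the data. Genes used for the sort were taken out of the lists. With the sort genes H2-Aa, H2-Ab1 and H2-Eb1 included, the MHC class II list had a camera p of 1.05e-23 in pre-CD8 against CDP (8.89e-05 with an estimated correlation), not adjusted because this form of the list stood outside the tests. The labels number the arrays of each group, without saying what a number marks. Deviations from the group means correlated at r = 0.1 to 0.42 over all 13 same-number pairs outside CD172a DC and at r = -0.16 to 0.024 over the 8 pairs with it. By the rule of over 0.1 in every pair the numbers were read as pairing the 4 other groups, and values with the number as a block are given where they change a call. Between groups of 2 arrays both numbers give the same r (0.41 for pre-CD4 and pre-CD8), so the pairs are not all separate. In those 4 groups array 1 also had the widest interquartile range (2.86 in CDP, 2.74 in pre-CD4, 2.70 in pre-CD8, 2.59 in CD24 DC). In CD172a DC it had the narrower one (2.17 against 2.35). The spread of values on an array was not told apart from a shared number, so the pairing is not established.

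The lists held genes of cDC1, cDC2, shared cDC, progenitor, MHC class II and class I presentation, cell cycle, MYC and ribosome biogenesis, interferon-stimulated, Toll-like receptor, trafficking receptor, transcription factor, glycolysis, oxidative phosphorylation, cholesterol synthesis, tissue-dissociation stress and sex-linked genes. Others held markers of pDCs, monocytes and macrophages, neutrophils, B cells, T cells, NK cells, erythroid cells, megakaryocytes and platelets, and basophils, mast cells and eosinophils. The groups, designs, lists, alternatives and the rule for named genes were set before the data were examined. By that rule the text names, for each comparison, the 6 called genes with the largest log2 difference in each direction whose groups do not overlap, and up to 4 called members with the largest differences of each list it describes. Predicted models, clones, RIKEN and numbered Gm names, small RNAs, olfactory receptor genes and immunoglobulin or T cell receptor segments were left out. A panel (Irf8, Batf3, Id2, Nfil3, Zbtb46, Irf4, Klf4, Xcr1, Clec9a and Mki67) was given in every comparison and sort markers as group means. For the contrast between stages, the 6 largest in each direction were named without the overlap condition.

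The tests were run on simulated data first, with 200 of 22184 genes changed by a log2 difference of 1 or 2. Of those changed by 2, from 86% (CD24 DC against pre-CD8) to 95% (CD24 DC against CD172a DC) were recovered, and of those changed by 1 from 15% (CD172a DC against pre-CD4) to 43% (CD24 DC against CD172a DC), with 3 to 8 false calls per comparison. Alternatives were quantile normalization, centring on array medians, filters on dim genes, the mean of a gene's probe sets, all probe sets, eBayes with trend and robust settings, fits of only the groups compared, at least a 2-fold change, treat against 1.5-fold, array weights, the replicate number as a block, and leaving out each array. The interquartile range of each array as a covariate, leaving out the 5 arrays numbered 1, and a simulation with deviations shared by number were added after the data were seen.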

Results

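Gene expression was measured on 12 Affymetrix whole-transcript arrays in dendritic cells (DCs) and DC progenitors of mice with a GFP reporter at 1 allele of Zbtb46, a transcription factor gene of classical DCs. The mice were on a C57Bl/6 background and were analysed at steady state. The 5 populations were sorted, to a purity above 95% per the series description. The common DC progenitor (CDP, n = 3), the pre-CD4 DC progenitor (n = 2) and the pre-CD8 DC progenitor (n = 2) came from bone marrow. The CD172a DC (n = 2) and the CD24 DC (n = 3) came from spleen. CD24 DCs and CD172a DCs correspond to the lineages usually called cDC1 and cDC2. The design set the progenitors against CDPs, against each other and against the mature population of their lineage. P-values of genes measure only the spread between these arrays, which can be technical. The labels did not make clear whether arrays of a group came from separate mice or pools. Camera p-values of lists rest on the spread across genes and, in the main form, on the preset correlation of 0.01. With estimated correlations (0.267 for cDC1 genes, 0.554 for cell cycle genes) the called list tests fell from 85 to 16.

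Each array gave 35145 probe-set values, from which 22184 named genes were tested. Array means were 5.28 to 5.34 (log2) and medians 4.89 to 5.24. The interquartile range was 2.48 to 2.86 on progenitor and 2.10 to 2.59 on mature arrays. Over all probe sets, arrays of the same group correlated at r = 0.925 to 0.987 (median 0.966 over 9 pairs), and arrays of different groups at r = 0.858 to 0.976 (median 0.932 over 57 pairs). Arrays of a group were not always the closest. Each pre-CD8 array correlated more with the pre-CD4 array of its number (r = 0.970 and 0.976) than with the other pre-CD8 array (0.963). CD24 DC 1 correlated at 0.957 with CD24 DC 2 and 0.925 with CD24 DC 3, against 0.947 with pre-CD8 1. The number of arrays limits the precision of every value. The median standard error of a log2 difference was 0.24 for comparisons of 3 arrays with 2 and 0.27 for those of 2 with 2.

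**Figure D1:**
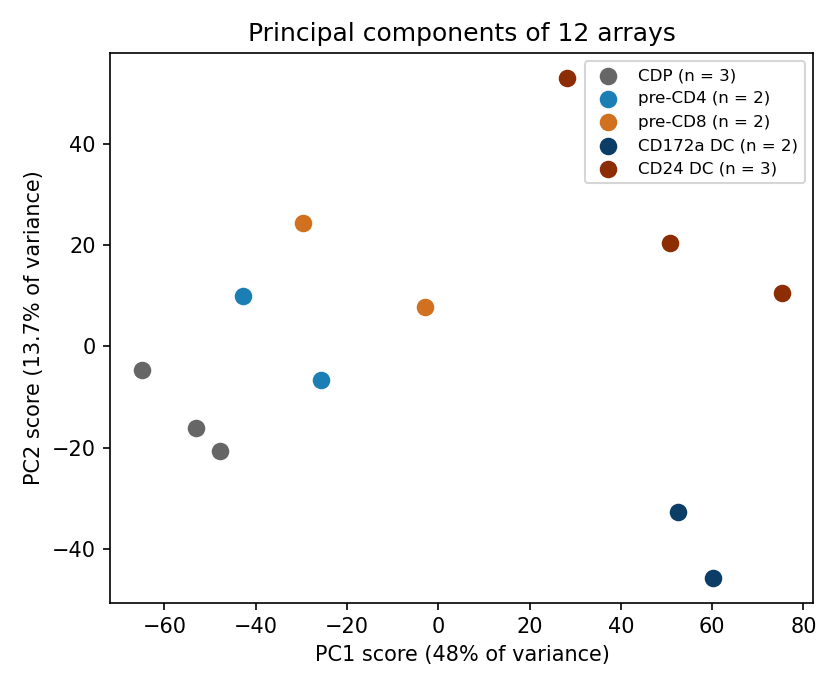
Scores of the 12 arrays on the leading principal components of the gene values (unitless scores), coloured by group, each point an array. PC1 took 48% of the variance and PC2 13.7%; the 7 bone marrow arrays lie at negative PC1 scores and the 5 spleen arrays at positive ones.

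Transcripts of the proteins used for sorting were given as group means ± SD, as a check of the labels. Kit, which encodes CD117, stood at 8.24 ± 0.25 in CDP, 5.95 ± 0.22 in pre-CD4 and 9.04 ± 0.27 in pre-CD8 arrays, and the gate was intermediate for CDP and pre-CD8 and low for pre-CD4. Csf1r, the gene of CD115, stood at 9.14 ± 0.13, 8.80 ± 0.04 and 6.53 ± 0.28, with CD115 required for CDP and pre-CD4. Flt3, the gene of CD135, stood at 9.52 ± 0.26, 9.55 ± 0.03 and 9.36 ± 0.24. Itgax, the gene of CD11c, was 6.07 ± 0.20 in CDP, which was gated negative, and 9.60 ± 0.09 and 7.97 ± 0.55 in pre-CD4 and pre-CD8, gated positive. Siglech was 8.29 ± 0.35 in pre-CD4, where Siglec H was not part of the gate, and 5.74 ± 0.31 in pre-CD8, where it was gated out. Sirpa, the gene of CD172a, was 9.35 ± 0.01 in CD172a DC and 5.85 ± 0.17 in CD24 DC, and Cd24a 10.34 ± 0.48 and 11.61 ± 0.21. The labels give CD24 DC as negative for MHC class II, yet H2-Ab1, an MHC class II chain, stood at 12.19 ± 0.15 there and at 11.92 ± 0.19 in CD172a DC. In CDP it was 6.59 ± 0.16, in pre-CD4 9.18 ± 1.44 and in pre-CD8 11.77 ± 0.29. Pre-CD4 cells were gated negative for MHC class II, as CDPs were, so the higher transcript level there does not match the gate. The pre-CD4 arrays also differed widely in this gene (SD 1.44).

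Differences are log2 differences ± standard error from limma, with p-values adjusted over all genes. A gene was called at an adjusted p under 0.05. For every called gene of the 6 comparisons, the arrays of the compared groups did not overlap. Chance gives that in 20% of genes for 3 arrays against 2 and in 33.3% for 2 against 2. Sirpb1a, Sirpb1c, the Clec4a and Ly6c genes, Cd209d, Ifi205, Ms4a6c, Gpr141b, the histone gene H2ac15 and the classical MHC genes belong to families of near-identical copies, and their values are uncertain.

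**Figure D2:**
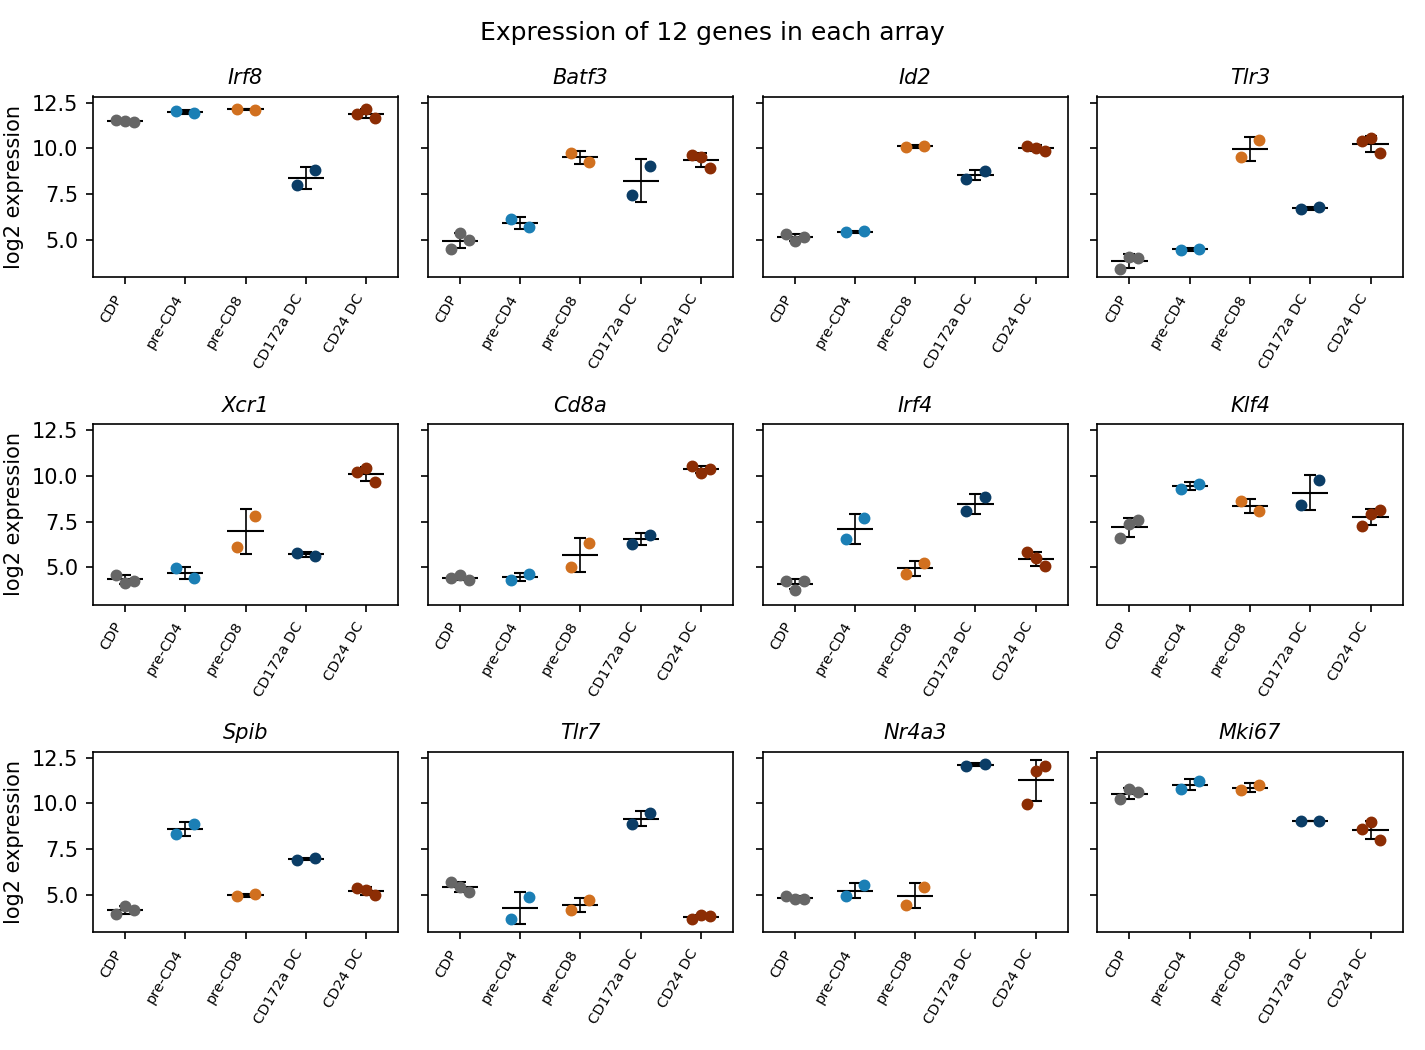
Log2 expression of 12 genes on each array, by group, with points for arrays, a line at the group mean and bars of 1 SD. Irf8 stands at 8.39 in CD172a DC and between 11.49 and 12.14 in the other groups; Id2 is at 5.43 in pre-CD4 and 10.10 in pre-CD8.

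Pre-CD8 progenitors were compared with CDPs (n = 2 against 3) to ask which genes separate the bone marrow progenitor of CD8 DCs from its precursor. Tlr3, an endosomal receptor for double-stranded RNA, was 6.15 ± 0.31 higher in pre-CD8, with group means of 3.84 in CDP and 9.98 in pre-CD8 (adjusted p = 2.01e-07). Id2, an inhibitor of E proteins needed for cDC1 development, was 4.96 ± 0.20 higher (adjusted p = 3.93e-08), and Batf3, an AP-1 factor of the same lineage, 4.55 ± 0.41 (adjusted p = 2.83e-05). The other largest rises were H2-Aa (6.47 ± 0.41), Plbd1 (5.80 ± 0.31), Ifi205 (5.65 ± 0.25), H2-Eb1 (5.39 ± 0.28) and Slamf7 (5.29 ± 0.23). H2-Aa and H2-Eb1 encode MHC class II chains, intermediate MHC class II being part of the pre-CD8 gate, and Slamf7 is a SLAM family receptor. The largest falls were F13a1 (-3.89 ± 0.23), Dntt (-3.84 ± 0.42), Sox4 (-3.50 ± 0.44), Il12a (-3.43 ± 0.36), Tfec (-3.42 ± 0.32) and Slpi (-3.42 ± 0.39). F13a1 encodes a coagulation factor subunit of monocytic cells, Dntt terminal deoxynucleotidyl transferase and Il12a a subunit of interleukin-12.

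Of 27 measured cDC1 genes, 21 rose and none fell, with 25 called higher when adjusted over the list alone. Their median difference was 2.20 (adjusted p = 2.06e-36, and 0.0299 with an estimated correlation), with Tlr3, Id2, Batf3 and Naaa (4.38 ± 0.30) as the largest. Shared cDC genes rose in 14 of 25, 15 when adjusted over the list alone (adjusted p = 6.92e-20, and 0.0189 with an estimated correlation). They included P2ry10 (4.58 ± 0.32), Anpep (4.01 ± 0.31) and Adam19 (3.52 ± 0.29), beside Slamf7. MHC class II presentation genes outside the sort markers rose in 8 of 14, 12 when adjusted over the list alone (adjusted p = 1.7e-14, and 0.0142 with an estimated correlation). The class II transactivator Ciita was 3.20 ± 0.28 higher and the costimulatory gene Cd86 3.01 ± 0.31. Progenitor genes fell in 12 of 26, 15 when adjusted over the list alone (adjusted p = 3.89e-18, and 0.0142 with an estimated correlation). Sox4 led these, followed by Adgrl4 (-3.30 ± 0.34), Ctsg (-3.20 ± 0.30) and Cd34 (-3.17 ± 0.31), Ctsg being the granule protease cathepsin G.

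MYC and ribosome biogenesis genes fell in 9 of 20, 14 when adjusted over the list alone (adjusted p = 1.16e-13, and 0.0836 with an estimated correlation), led by Cad (-1.25 ± 0.20) and Gnl3 (-1.20 ± 0.22). Toll-like receptor genes rose in 6 of 18 and none fell, with 9 higher and 1 lower when adjusted over the list alone. The list had an adjusted p of 1e-05 (0.131 with an estimated correlation), with Tlr3 and Tlr11 (3.02 ± 0.41) the largest. Of the markers of basophils, mast cells and eosinophils, 3 of 10 were higher in pre-CD8 (adjusted p = 0.000366, and 0.302 with an estimated correlation), among them Prg2 (2.46 ± 0.57) and Cpa3 (1.77 ± 0.28). In the panel given in every comparison, Zbtb46 (1 reporter allele in every group) rose by 1.74 ± 0.23 and the chemokine receptor gene Xcr1 by 2.61 ± 0.40. Irf8 differed by 0.65 ± 0.24, Nfil3 by -0.57 ± 0.39, Irf4 by 0.86 ± 0.35, Klf4 by 1.16 ± 0.39 and the proliferation gene Mki67 by 0.33 ± 0.28, none of them called, though Klf4 was with the replicate number as a block (1.34, adjusted p = 0.0347). In all, 1057 genes changed, 509 higher and 548 lower in pre-CD8, and 15 of 26 fixed lists were called, 4 of them also with an estimated correlation. The count was 668 without CDP array 1, 654 without CDP array 3, 574 without pre-CD8 array 1 and 510 without pre-CD8 array 2, there with 305 higher and 205 lower. Prg2 lost its call without CDP array 1 (adjusted p = 0.0965), CDP array 3 (0.0839) or pre-CD8 array 2 (0.271, with a difference of 1.17, and of 3.74 without pre-CD8 array 1), and the basophil list lost its own without pre-CD8 array 2 (adjusted p = 0.0679). Without the 5 arrays numbered 1, 297 higher and 205 lower genes were called. Other called lists, besides those of the closing part, were those of cell cycle (median -0.0707, adjusted p = 0.00796, and 0.614 with an estimated correlation), oxidative phosphorylation (-0.215, 0.0027 and 0.544) and NK cell (0.394, 0.0137 and 0.372) genes. On leaving out an array, calls were lost for the cell cycle list without pre-CD8 2 (0.0564), the oxidative phosphorylation list without pre-CD8 2 (0.203) and the NK cell list without pre-CD8 2 (0.173). Calls ended without the 5 arrays numbered 1 for Cad (0.0514) and Gnl3 (0.149) and with the interquartile covariate for the cell cycle list (0.464), the oxidative phosphorylation list (0.424) and the NK cell list (0.0921) (adjusted p in brackets). Calls also ended with the filter on dim genes at the 40th percentile for the NK cell list (0.0555) and over every probe set for Prg2 (0.0564). They ended too in the fit of only the groups compared for Prg2 (0.119) and under treat for Cad, Gnl3 and Prg2 (0.173 to 0.317). They ended as well with fry for the cell cycle list, the oxidative phosphorylation list, the NK cell list and the basophil list (0.0572 to 0.353).

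Pre-CD4 progenitors were compared with CDPs in the same way (n = 2 against 3). Cd7, an immunoglobulin superfamily receptor, was 5.56 ± 0.50 higher in pre-CD4, with group means of 5.58 in CDP and 11.14 in pre-CD4 (adjusted p = 4.42e-05). The lectin gene Cd209d was 4.75 ± 0.36 higher (adjusted p = 1.61e-05) and Spib, an ETS factor of plasmacytoid DCs and B cells, 4.38 ± 0.22 (adjusted p = 7.74e-07). Plbd1 (4.46 ± 0.31), Slamf7 (4.04 ± 0.23) and H2-Aa (3.79 ± 0.41) made up the rest of the 6 largest rises. H2-Aa encodes an MHC class II chain, although pre-CD4 cells, like CDPs, were gated negative for MHC class II. The largest falls were Ctsg (-4.92 ± 0.30), Mpo (-4.91 ± 0.43), Dntt (-4.64 ± 0.42), Tfec (-4.38 ± 0.32), Elane (-3.80 ± 0.61) and Muc13 (-3.77 ± 0.33), Mpo encoding myeloperoxidase and Elane neutrophil elastase. Irf4, a factor of the cDC2 lineage, rose by 3.00 ± 0.35 (adjusted p = 0.000306) and Klf4 by 2.25 ± 0.39 (adjusted p = 0.00468).

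Progenitor genes fell in 13 of 26, 16 when adjusted over the list alone (adjusted p = 3.72e-19, and 0.0142 with an estimated correlation), led by Ctsg, Mpo, Elane and Muc13. MYC and ribosome biogenesis genes fell in 13 of 20, 18 when adjusted over the list alone (adjusted p = 1.38e-21, and 0.0469 with an estimated correlation), the largest being the nucleolar GTPase gene Gnl3 (-1.66 ± 0.22). Shared cDC genes rose in 11 of 25, 11 when adjusted over the list alone (adjusted p = 1.41e-10, and 0.0469 with an estimated correlation), with Adam19 (3.52 ± 0.29), Cd200r1 (3.41 ± 0.32) and P2ry10 (3.10 ± 0.32) after Slamf7. The MHC class II presentation list had 4 of 14 called higher, 10 when adjusted over the list alone (adjusted p = 5.99e-08, and 0.0342 with an estimated correlation), the thiol reductase gene Ifi30 leading at 3.00 ± 0.38. Of 27 cDC2 genes, 6 rose and 1 fell, 7 and 2 when adjusted over the list alone (adjusted p = 0.00486, and 0.35 with an estimated correlation), led by Irf4 and S100a4 (2.29 ± 0.36).

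Markers of plasmacytoid DCs (pDCs) rose in 5 of 16 and fell in 1, 7 and 1 when adjusted over the list alone (adjusted p = 1.56e-05, and 0.0311 with an estimated correlation). Dntt was the member that fell, and Spib and Upb1 (3.01 ± 0.41) rose the most. The cDC1 list was called with 3 of 27 higher and 1 lower (adjusted p = 0.046, and 0.602 with an estimated correlation), a call lost without CD24 DC 1 or 3, CDP 1 or 3, or pre-CD4 1 or 2 (adjusted p up to 0.0795), and with the replicate number as a block (adjusted p = 0.183). Its panel members gave 0.49 ± 0.24 for Irf8, 0.97 ± 0.41 for Batf3, 0.29 ± 0.20 for Id2 and 0.34 ± 0.40 for Xcr1, none of them called, while Nfil3 fell by 1.49 (standard error 0.39, adjusted p = 0.045). Zbtb46 rose by 1.29 ± 0.23, and Mki67 differed by 0.48 ± 0.28 without a call. A total of 1008 genes changed, 514 higher and 494 lower in pre-CD4, and 13 of 26 lists were called, 5 of them also with an estimated correlation. The count was 618, 666 and 592 without CDP array 1, 2 and 3, and 452 and 298 without pre-CD4 array 1 and 2. Without pre-CD4 array 2 the adjusted p was 0.0559 for Elane and 0.0744 for Klf4, without pre-CD4 array 1 it was 0.0824 for Zbtb46, and Nfil3 lost its call without any array other than CD24 DC 1 and 3 (adjusted p from 0.0508 to 0.232). Another called list was that of oxidative phosphorylation (median -0.338, adjusted p = 0.00203, and 0.526 with an estimated correlation) genes. On leaving out an array, calls were lost for the oxidative phosphorylation list without pre-CD4 2 (0.137). Further calls ended without the 5 arrays numbered 1 for Gnl3 (0.0571), Zbtb46 (0.133) and the cDC1 list (0.0647) and with the interquartile covariate for the cDC1 list (0.0511) (adjusted p in brackets). Further ones ended with quantile normalization for Nfil3 (0.128) and with the filter on dim genes at the 40th percentile for the cDC1 list (0.0512). They ended too over every probe set for Nfil3 (0.0923) and under treat for Klf4, Nfil3 and Zbtb46 (0.0537 to 0.706). They ended as well with fry for the cDC1 list and the oxidative phosphorylation list (0.271 to 0.284).

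The changes of both progenitors from CDP were set against each other. Of the genes higher than in CDP, 279 were called in both, against 11.8 for independent lists, and of the lower ones 308, against 12.2. Across genes, which are not independent replicates, the differences correlated at r = 0.725 (Spearman's rho 0.657), and r = 0.401 in simulations of unchanged groups against the same 3 CDP arrays. The covariance was 0.168 against 0.0293 in the simulations. Simulated with deviations also shared between arrays of the same number (r = 0.388), unchanged groups gave r = 0.467 and a covariance of 0.0235. The CDP arrays are too few to split, and part of the excess in r and in shared calls can come from them.

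The progenitors were compared directly (pre-CD8 against pre-CD4, n = 2 each) to ask what separates them before the mature stage. Tlr3 was 5.51 ± 0.34 higher in pre-CD8 (adjusted p = 5.16e-06) and Id2 4.67 ± 0.22 (adjusted p = 2.77e-07). Rab7b, a small GTPase of endosomal transport, was 4.02 ± 0.32 higher and Batf3 3.58 ± 0.45, with Gpr141b (4.03 ± 0.53) and H2-Eb1 (3.90 ± 0.31) the other largest rises. Higher in pre-CD4 were Spib, at -3.60 ± 0.24 as pre-CD8 minus pre-CD4 (adjusted p = 8.45e-06), and Cd7 (-3.69 ± 0.55), Atp1b1 (-3.59 ± 0.26), Cd209d (-3.55 ± 0.39), Upk1b (-3.49 ± 0.29) and Lifr (-3.12 ± 0.32), Atp1b1 encoding a sodium pump subunit and Lifr the receptor of leukemia inhibitory factor. Irf4 was also lower in pre-CD8, at -2.15 ± 0.39 (adjusted p = 0.0191).

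Of the cDC1 genes, 15 of 27 were higher in pre-CD8 and none lower, 20 when adjusted over the list alone, with a median of 2.04 (adjusted p = 4.05e-54, and 0.0144 with an estimated correlation). Tlr3, Id2, Rab7b and Batf3 were the largest. The cDC2 list had no member higher and 2 of 27 lower, 4 when adjusted over the list alone. It was called as lower although its median was 0.0247 (adjusted p = 0.0405, and 0.492 with an estimated correlation); it was not called without CD24 DC 1, 2 or 3, CDP 1, pre-CD4 2 or pre-CD8 1 (adjusted p up to 0.896). Its members called over all genes were Irf4 and the fractalkine receptor gene Cx3cr1 (-1.49 ± 0.23). Markers of pDCs were lower in pre-CD8 in 4 of 16 and none was higher, with 10 lower and 1 higher when adjusted over the list alone. Their median was -1.20 (adjusted p = 1.7e-14, and 0.0104 with an estimated correlation). The E protein gene Tcf4 (-1.91 ± 0.21) followed Spib. Shared cDC genes were higher in 4 of 25 and lower in 1 (adjusted p = 2.99e-07, and 0.0836 with an estimated correlation), with Rab30 (3.21 ± 0.31), Cd200r1 (-2.73 ± 0.36) and Fgl2 (2.44 ± 0.28). MHC class II presentation genes were higher in 3 of 14 and lower in 1 (adjusted p = 1.56e-05, and 0.0611 with an estimated correlation).

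Lists of granulocyte and NK cell markers were called in the same comparison. Basophil, mast cell and eosinophil markers were higher in pre-CD8 in 2 of 10, 6 when adjusted over the list alone (adjusted p = 1.32e-10, and 0.0736 with an estimated correlation), the called ones being the granule genes Prg2 (3.26 ± 0.63) and Cpa3 (1.72 ± 0.30). Prg2 read 6.35 and 8.91 on the pre-CD8 arrays. Neutrophil markers had a median of 1.29 with no called member (adjusted p = 0.0161, and 0.574 with an estimated correlation), and NK cell markers one of 0.33 with none (adjusted p = 0.000618, and 0.239 with an estimated correlation). Without pre-CD8 array 2 the neutrophil median was -0.262 (adjusted p = 0.152) and the NK cell list was not called (adjusted p = 0.0511), and without pre-CD4 array 1 the adjusted p of the neutrophil list was 0.275. Xcr1 was 2.27 ± 0.43 higher in pre-CD8 (adjusted p = 0.0296). The panel genes Irf8 (0.15 ± 0.26), Nfil3 (0.92 ± 0.42), Zbtb46 (0.45 ± 0.25), Klf4 (-1.09 ± 0.43) and Mki67 (-0.16 ± 0.30) were not called. In total 156 genes changed, 85 higher and 71 lower in pre-CD8, and 12 of 26 lists were called, 2 of them, cDC1 genes and pDC markers, also with an estimated correlation. The count was 64 and 82 without pre-CD4 array 1 and 2 and 58 without pre-CD8 array 2, and these arrays or others ended the calls of Cd7 (pre-CD4 1 or pre-CD8 2, adjusted p up to 0.0804), Irf4 (pre-CD4 2, pre-CD8 1 or pre-CD8 2, adjusted p up to 0.225), Xcr1 (a difference of 1.40 without pre-CD8 2; CD172a DC 1, CD172a DC 2, CDP 3, pre-CD4 1, pre-CD4 2 or pre-CD8 2, adjusted p up to 0.259), Cx3cr1 (pre-CD4 1 or pre-CD8 2, adjusted p up to 0.107), Prg2 (a difference of 1.98 without pre-CD8 2; CD172a DC 1, CD172a DC 2, CD24 DC 2, CD24 DC 3, pre-CD4 1, pre-CD4 2 or pre-CD8 2, adjusted p up to 0.236) and Cpa3 (pre-CD4 1 or pre-CD8 2, adjusted p up to 0.254). Without the 5 arrays numbered 1 there were 60 higher and 29 lower. The remaining called lists outside the closing part were those of MHC class I presentation (median 0.329, adjusted p = 0.000466, and 0.22 with an estimated correlation), MYC (0.352, 0.00016 and 0.35) and Toll-like receptor (0.217, 8e-05 and 0.186) genes. Calls of this comparison ended without the 5 arrays numbered 1 for Cpa3 (0.134), Cx3cr1 (0.111), Tcf4 (0.0597) and the cDC2 list (0.142) and with the interquartile covariate for the cDC2 list (0.0556) and the neutrophil list (0.114) (adjusted p in brackets). Losses also came with quantile normalization for Prg2, Xcr1 and the cDC2 list (0.0513 to 0.0686) and with the filter on dim genes at the 40th percentile for the cDC2 list (0.0752). They ended too over every probe set for Ctsg, Irf4, Prg2 and Xcr1 (0.0544 to 0.0813) and in the fit of only the groups compared for Cd7, Cpa3, Ctsg, Cx3cr1, Fgl2, Gpr141b, Irf4, Lifr, Prg2 and Xcr1 (0.0697 to 0.348). They ended as well under treat for Cpa3, Ctsg, Cx3cr1, Irf4, Prg2 and Xcr1 (0.134 to 0.455) and with fry for the cDC2 list, the MHC class I presentation list, the MYC list, the neutrophil list and the NK cell list (0.0597 to 0.539).

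The mature populations were compared as CD24 DC against CD172a DC (n = 3 against 2). Irf8, a factor of the cDC1 lineage, was 3.51 ± 0.24 higher in CD24 DC, 11.4-fold (adjusted p = 2.43e-06), and Xcr1 4.39 ± 0.40 (adjusted p = 2.17e-05). The other largest rises were Gpr141b (4.81 ± 0.49), P3h2 (4.17 ± 0.36), Rab7b (4.11 ± 0.30), Ifi205 (4.09 ± 0.25) and Cd36 (4.02 ± 0.34), Cd36 encoding a scavenger receptor. Higher in CD172a DC were the single-stranded RNA sensor gene Tlr7, at -5.36 ± 0.33 (adjusted p = 1.19e-06), and the receptor genes Sirpb1c (-7.00 ± 0.33), Clec4a1 (-5.55 ± 0.28), Sirpb1a (-5.28 ± 0.33), Clec4a4 (-5.23 ± 0.24) and Clec4a3 (-5.17 ± 0.78). Irf4 stood at -2.99 ± 0.35 (adjusted p = 0.000206), higher in CD172a DC.

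In CD24 DC, 23 of 27 cDC1 genes were higher and none lower, 26 when adjusted over the list alone, with a median of 2.74 (adjusted p = 1.33e-43, and 0.02 with an estimated correlation). Cd8a (3.83 ± 0.32) stood beside Xcr1, Rab7b and Cd36. Genes of cDC2 were lower in 9 of 27 and higher in 1, 16 and 1 when adjusted over the list alone (adjusted p = 1.41e-10, and 0.062 with an estimated correlation), led by Tlr7, Clec4a4, the decoy receptor gene Il1r2 (-4.11 ± 0.61) and the integrin gene Itgam (-3.06 ± 0.36). MHC class I presentation genes were higher in 9 of 18 and lower in 1, 14 and 1 when adjusted over the list alone (adjusted p = 2.99e-09, and 0.0611 with an estimated correlation). The member that was lower was the NADPH oxidase gene Cybb (-3.46 ± 0.61), and H2-K1 (1.82 ± 0.44), Tap2 (1.42 ± 0.29) and Calr (1.40 ± 0.20) were the largest of the rest. Interferon-stimulated genes were higher in 2 of 20 and lower in 5 (adjusted p = 0.0106, and 0.492 with an estimated correlation), with the antiviral genes Oas2 (-2.78 ± 0.36) and Ddx58 (-2.08 ± 0.29). Oxidative phosphorylation genes were higher in 3 of 23, 9 when adjusted over the list alone (adjusted p = 1.15e-05, and 0.372 with an estimated correlation). Monocyte and macrophage markers were higher in 1 of 17 and lower in 3 (adjusted p = 0.00271, and 0.321 with an estimated correlation); the largest was Adgre1, the gene of F4/80, at -3.75 ± 0.28.

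Id2 was 1.48 ± 0.20 higher in CD24 DC, and the panel genes Batf3 (1.10 ± 0.41), Nfil3 (-0.21 ± 0.39), Zbtb46 (0.56 ± 0.23), Klf4 (-1.32 ± 0.39) and Mki67 (-0.51 ± 0.28) were not called. Klf4 was called without CD172a DC 1 (adjusted p = 0.0247), without the 5 arrays numbered 1 (0.0109), with the replicate block (0.0179), with array weights (0.0277) and with the filter on dim genes at the median (0.0489). Batf3 was called without CD172a DC 2 (1.92, adjusted p = 0.0161) and with array weights (0.0318). The comparison gave 1239 changed genes, 713 higher and 526 lower in CD24 DC, and 7 of 26 lists were called, cDC1 genes also with an estimated correlation. Without CD172a DC array 1 the count was 556 and the balance turned, with 255 higher and 301 lower, as it did without the 5 arrays numbered 1 (209 higher and 299 lower). H2-K1 lost its call without CD172a DC 1, CD24 DC 1 or CD24 DC 3 (adjusted p = 0.282, 0.0662 and 0.0624) and Tap2 without CD172a DC 1 or 2 (0.0875 and 0.0766), with a difference of H2-K1 of 0.75 without CD172a DC 1 and 2.89 without CD172a DC 2, and the interferon list without CD172a DC 2 or CD24 DC 3 (0.216 and 0.199). The oxidative phosphorylation median fell from 0.48 to 0.137 without the 5 arrays numbered 1. The last called list was that of MYC (median 0.224, adjusted p = 0.0248, and 0.564 with an estimated correlation) genes. On leaving out an array, calls were lost for the MYC list without CD172a DC 1, CD24 DC 1 or CD24 DC 2 (0.126 to 0.201). Calls were also lost without the 5 arrays numbered 1 for H2-K1 (0.435), Id2 (0.0553), the MYC list (0.576) and the oxidative phosphorylation list (0.0834) and with the interquartile covariate for the MYC list (0.196) (adjusted p in brackets). Losses came too with quantile normalization for the MYC list (0.162) and with the filter on dim genes at the 40th percentile for the MYC list (0.0583). They ended too in the fit of only the groups compared for H2-K1 (0.0967) and under treat for H2-K1 and Tap2 (0.273 to 0.29). They ended as well with fry for the MYC list, the interferon list and the oxidative phosphorylation list (0.0838 to 0.194).

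**Figure D3:**
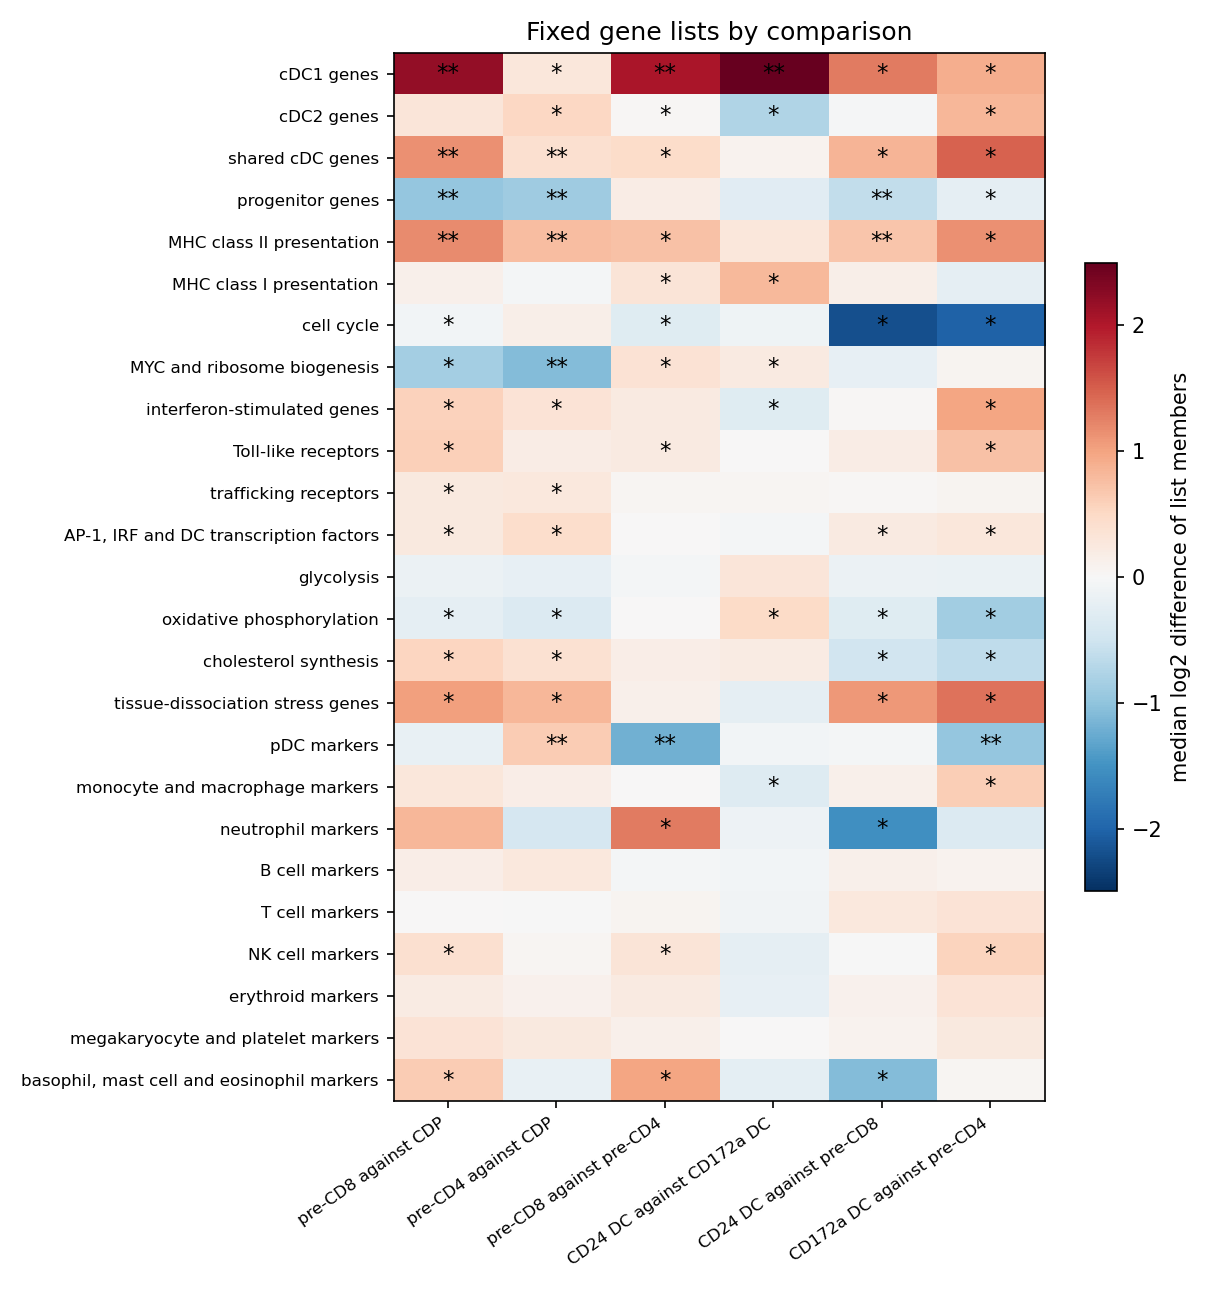
Median log2 difference of the measured members of 25 gene lists (colour) in the 6 comparisons. A star marks an adjusted camera p under 0.05 with the preset correlation and a pair of stars a p under 0.05 with an estimated correlation as well; cDC1 genes reach medians of 2.20, 2.04 and 2.74 in pre-CD8 against CDP, pre-CD8 against pre-CD4 and CD24 DC against CD172a DC.

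The step from pre-CD8 to CD24 DC (n = 2 and 3) combined a change of stage with a change of tissue, from bone marrow to spleen. Cell cycle genes fell: Mki67 stood at -2.33 ± 0.28 (adjusted p = 0.000138), and 20 of 28 list members were lower in CD24 DC and none higher, 25 when adjusted over the list alone (median -2.19, adjusted p = 4.99e-31, and 0.0836 with an estimated correlation). The mitotic genes Kif11 (-3.04 ± 0.34), Birc5 (-2.97 ± 0.33), Ccna2 (-2.96 ± 0.24) and Cenpe (-2.90 ± 0.24) led them. The largest rise was that of the orphan nuclear receptor gene Nr4a3, by 6.30 ± 0.48 (adjusted p = 7.97e-06), followed by Apol7c (5.87 ± 0.44), Dnase1l3 (5.82 ± 0.32), Adam23 (5.80 ± 0.32), Il1b (5.58 ± 0.32) and Rasgef1b (5.04 ± 0.38). Dnase1l3 encodes a secreted DNase and Il1b interleukin-1 beta. The largest falls were S100a10 (-3.97 ± 0.43), Mcpt8 (-3.91 ± 0.55), Mpo (-3.78 ± 0.43), Bex6 (-3.73 ± 0.44), Ms4a6c (-3.70 ± 0.45) and Cd226 (-3.62 ± 0.27), Mcpt8 being a basophil protease.

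Genes of cDC1 rose further in 14 of 27, 18 when adjusted over the list alone (adjusted p = 1.7e-14, and 0.0912 with an estimated correlation), with Cd8a (4.68 ± 0.32), Cadm1 (3.89 ± 0.34), Itgae (3.23 ± 0.34) and Xcr1 (3.14 ± 0.40). The transcription factor genes of the panel were not called, at -0.24 ± 0.24 for Irf8, -0.16 ± 0.41 for Batf3, -0.08 ± 0.20 for Id2, 1.18 ± 0.39 for Nfil3, 0.18 ± 0.23 for Zbtb46, 0.52 ± 0.35 for Irf4 and -0.59 ± 0.39 for Klf4; Nfil3 was called without CD24 DC 1 (1.68, adjusted p = 0.00118), without the 5 arrays numbered 1 (0.0443) and with array weights (0.00322). MHC class II presentation genes rose in 6 of 14, 8 when adjusted over the list alone (adjusted p = 1.88e-06, and 0.0469 with an estimated correlation); the largest were the costimulatory and maturation genes Cd80 (3.44 ± 0.37), Cd83 (3.39 ± 0.33) and Cd86 (2.68 ± 0.31). Shared cDC genes rose in 12 of 25, 14 when adjusted over the list alone (adjusted p = 2.14e-09, and 0.0611 with an estimated correlation), with Klri1 (3.83 ± 0.34) and Ccr7 (3.38 ± 0.48). Progenitor genes fell in 7 of 26, 9 when adjusted over the list alone (adjusted p = 2.57e-08, and 0.0403 with an estimated correlation), led by Mpo, with Elane (-3.54 ± 0.61) and Ctsg (-3.16 ± 0.30) next.

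Tissue-dissociation stress genes rose in 12 of 23, 14 when adjusted over the list alone (adjusted p = 6.16e-11, and 0.0912 with an estimated correlation), led by the immediate-early genes Nr4a1 (4.33 ± 0.37) and Egr2 (4.0 ± 0.46); only the spleen was digested with enzymes. Basophil, mast cell and eosinophil markers fell in 5 of 10 (adjusted p = 1.51e-06, and 0.15 with an estimated correlation). The neutrophil list, with no called member, had a median of -1.53 (adjusted p = 0.00321, and 0.496 with an estimated correlation). Cholesterol synthesis genes had a median of -0.48 with no called member (adjusted p = 0.000285, and 0.321 with an estimated correlation). The step changed 1399 genes, 587 higher and 812 lower in CD24 DC, with 11 of 26 lists called and 2 of them also with an estimated correlation. The count was 571 without pre-CD8 array 1. The neutrophil list was not called without CD24 DC 1 (adjusted p = 0.0591) or pre-CD8 2 (median 0.144, adjusted p = 0.974). The remaining called lists were those of transcription factor (median 0.233, adjusted p = 0.0148, and 0.344 with an estimated correlation) and oxidative phosphorylation (-0.294, 0.0108 and 0.579) genes. On leaving out an array, the oxidative phosphorylation list lost its call without CD24 DC 3 or pre-CD8 1. Its median ran from -0.515 without pre-CD8 2 to -0.0887 without pre-CD8 1. Calls in this step ended with the interquartile covariate for the cholesterol synthesis list (0.0574) and the oxidative phosphorylation list (0.987) (adjusted p in brackets). The latter turned direction there, with a median of 0.023. With quantile normalization the call of the oxidative phosphorylation list ended as well (0.0921). They also ended with the filter on dim genes at the 40th percentile for the oxidative phosphorylation list and the neutrophil list (0.058 to 0.0668) and with fry for the oxidative phosphorylation list, the cholesterol synthesis list and the neutrophil list (0.0764 to 0.315).

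The step from pre-CD4 to CD172a DC (n = 2 each) likewise joined stage and tissue. Irf8 fell, at -3.60 ± 0.26 (adjusted p = 2.22e-06), while Id2 rose by 3.10 ± 0.22 (adjusted p = 1.88e-06), Batf3 by 2.31 ± 0.45 (adjusted p = 0.0039), Nfil3 by 2.31 ± 0.42 and Irf4 by 1.36 ± 0.39. Nr4a3 rose by 6.87 ± 0.53, Il1b by 6.80 ± 0.35 and the prostaglandin synthase gene Ptgs2 by 6.64 ± 0.26, with Rasgef1b (6.19 ± 0.42), Sirpb1c (5.92 ± 0.36) and Adam23 (5.89 ± 0.35) the other largest rises. The monocyte surface gene Ly6c2 fell the most, at -7.25 ± 0.43 (adjusted p = 7.27e-07), ahead of H2ac15 (-6.17 ± 1.10), Fn1 (-5.02 ± 0.43), Lgals1 (-4.97 ± 0.46), H2ax (-4.86 ± 0.32) and Gria3 (-4.58 ± 0.40), H2ac15 and H2ax being histone genes and Fn1 fibronectin.

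Cell cycle genes fell in 23 of 28 and none rose, 27 when adjusted over the list alone (median -2.03, adjusted p = 8.5e-24, and 0.12 with an estimated correlation), with Birc5 (-3.90 ± 0.36), Plk1 (-3.30 ± 0.27) and Aurkb (-3.07 ± 0.30); Mki67 was -1.98 ± 0.30. Of the cDC2 genes, 11 of 27 rose and 6 fell, 12 and 6 when adjusted over the list alone (adjusted p = 0.0169, and 0.42 with an estimated correlation): Il1r2 (5.73 ± 0.67), Clec4a4 (5.42 ± 0.26) and Tlr7 (4.90 ± 0.36) rose and the chemokine receptor gene Ccr2 (-3.61 ± 0.40) fell. Shared cDC genes rose in 15 of 25 and fell in 3 (adjusted p = 1.67e-08, and 0.0652 with an estimated correlation), with H2-Eb2 (4.91 ± 0.47), Rab30 (4.89 ± 0.31) and Klri1 (4.66 ± 0.37). MHC class II presentation genes rose in 7 of 14 and fell in 1 (adjusted p = 8.87e-05, and 0.077 with an estimated correlation), with Cd80 (5.0 ± 0.41), Cd86 (4.76 ± 0.35) and Cd83 (3.68 ± 0.37). Markers of pDCs rose in 1 of 16 and fell in 6, 1 and 11 when adjusted over the list alone (adjusted p = 5.75e-05, and 0.0342 with an estimated correlation), led by Upb1 (-3.35 ± 0.44), Bst2 (-3.34 ± 0.58) and Tcf4 (-2.03 ± 0.21). Genes of cDC1 rose in 10 of 27 and fell in 2 here too, with a median of 0.90 (adjusted p = 3.51e-05, and 0.35 with an estimated correlation), Irf8 being among those that fell and Id2, Tlr11 (2.66 ± 0.45) and Cd36 (2.32 ± 0.37) among those that rose.

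Oxidative phosphorylation genes fell in 10 of 23, 15 when adjusted over the list alone (adjusted p = 2.99e-07, and 0.327 with an estimated correlation), the largest being Ndufa9 (-2.06 ± 0.33). Stress genes of tissue dissociation rose in 15 of 23, 17 when adjusted over the list alone (adjusted p = 3.48e-11, and 0.0912 with an estimated correlation), led by Nr4a1 (4.95 ± 0.40) and Egr2 (4.13 ± 0.51), here too after enzymatic digestion of the spleen alone. Interferon-stimulated genes rose in 8 of 20 and fell in 2 (adjusted p = 0.0027, and 0.42 with an estimated correlation), Oas2 by 2.34 ± 0.39. Monocyte and macrophage markers rose in 7 of 17 and fell in 3 (adjusted p = 0.0226, and 0.42 with an estimated correlation); Adgre1 rose by 3.76 ± 0.30. NK cell markers had a median of 0.56 (adjusted p = 0.00232, and 0.302 with an estimated correlation), with the median at 0.161 with the interquartile covariate and 1 of 12 called, the chemokine gene Ccl5 (5.67 ± 0.42). The panel genes Zbtb46 (0.07 ± 0.25), Klf4 (-0.36 ± 0.43) and Xcr1 (1.02 ± 0.43) were not called, though Xcr1 was without pre-CD8 1 or 2 (adjusted p = 0.0346) and in the fit of only the groups compared (0.0286). This step changed 2821 genes, 1042 higher and 1779 lower in CD172a DC, 36.9% higher, and 15 of 26 lists were called, pDC markers also with an estimated correlation. The balance depended on the setting. With each array centred on its median 719 were higher and 2272 lower (24.0% higher), as the median of all genes moved from 0.0854 to -0.111. There were, however, 1175 higher and 1371 lower (46.2%) with quantile normalization, 674 higher and 662 lower (50.4%) with the interquartile range as a covariate and 497 higher and 499 lower (49.9%) without the 5 arrays numbered 1. The count was 1455 without CD172a DC array 1, 1233 without pre-CD4 array 1 and 1336 with the covariate. Without CD172a DC 1 H2ac15 stood at -3.80, and without CD172a DC 2 Batf3 was smaller but still called (adjusted p = 0.0398). Irf4 stood at 0.79 without pre-CD4 1. The cDC2 list lost its call without CD172a DC 2 (adjusted p = 0.0968), and Irf4 without CD172a DC 2, CD24 DC 2 or pre-CD4 1 (adjusted p = 0.22, 0.051 and 0.378). Further called lists were those of progenitor (median -0.234, adjusted p = 0.0256, and 0.327 with an estimated correlation), Toll-like receptor (0.732, 0.000568 and 0.25) and transcription factor (0.284, 0.0336 and 0.38) genes. On leaving out an array, calls were lost for the progenitor list without CD172a DC 2 or pre-CD4 1 (0.0835 to 0.0868) and the transcription factor list without CD172a DC 2 (0.24). In this step calls ended without the 5 arrays numbered 1 for Irf4 (0.135) and Ndufa9 (0.0548) and with the interquartile covariate for H2ac15 (0.0746), Irf4 (0.0795), Nfil3 (0.0928), the oxidative phosphorylation list (0.0806) and the monocyte list (0.0788) (adjusted p in brackets). Calls were lost too with median centring for Irf4 (0.0853) and over every probe set for Irf4 (0.058). They ended too in the fit of only the groups compared for Irf4 (0.0505) and under treat for Irf4 (0.429).

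The maturation steps share no array but 1 fit of each gene's spread. Both called 316 genes higher, against 27.6 for independent lists, and 571 lower, against 65.1. Across genes they correlated at r = 0.645 (Spearman's rho 0.543). Deviations shared by number were not allowed for, and no simulation was run. Tissue, digestion and interquartile range changed with stage in both steps, so the overlap need not be maturation. In no comparison did camera call the lists of B cell, T cell, erythroid, megakaryocyte and platelet, glycolysis and sex-linked genes. Their lowest adjusted camera p over the comparisons and the interaction was 0.0521, 0.0986, 0.0521, 0.0502, 0.118 and 0.507 in that order. With fry the B cell list was called in pre-CD8 (adjusted p = 0.0176) and pre-CD4 (0.024) against CDP, and in CD172a DC against pre-CD4 (0.0274). With the replicate number as a block, the megakaryocyte and platelet list was called in pre-CD8 against CDP (adjusted p = 0.042) and the erythroid list between stages (0.0336). Trafficking receptor genes and the list of AP-1, IRF and DC transcription factors were called against CDP in pre-CD8 (adjusted p = 0.0198 and 2.25e-05), neither with an estimated correlation (adjusted p = 0.126 and 0.107).

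The last comparison asked how far the difference between the mature lineages was present in the progenitors. The 512 genes higher in CD24 DC than in CD172a DC by at least 2-fold were higher in pre-CD8 than in pre-CD4 in 360 cases (70.3%), against 51.1% of other genes, with a median of 0.19 (camera p = 2.57e-14, and p = 0.0736 with an estimated correlation). The 419 genes higher in CD172a DC were higher in pre-CD8 in 159 cases (37.9%), against 51.8% of other genes, with a median of -0.15 (camera p = 9.15e-10, and p = 0.0195 with an estimated correlation). Without pre-CD4 array 2 the median of the CD24 DC genes was 0.105, and without the 5 arrays numbered 1 the medians were 0.502 over 209 genes and -0.304 over 299. The lists came from other arrays than the progenitor comparison, but a gene's spread was taken from all arrays in a single fit, so the comparisons are not independent. Of the genes called in both comparisons, 42 were higher in pre-CD8 and CD24 DC, where independent lists give 2.73, and 24 were higher in pre-CD4 and CD172a DC, where they give 1.68. The opposite pairings held 1 and 2 genes. Across all genes the lineage differences correlated at r = 0.208 and at a Spearman's rho of 0.0817.

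A test of the difference between stages, (pre-CD8 minus pre-CD4) minus (CD24 DC minus CD172a DC), called 229 genes. The largest positive differences were Sirpb1c (6.26 ± 0.49), Clec4a1 (5.94 ± 0.42), Clec4a4 (5.79 ± 0.36), Sirpb1a (5.63 ± 0.49), Tlr7 (5.55 ± 0.48) and Il1r2 (5.0 ± 0.90), all higher in CD172a DC than in CD24 DC and not called between the progenitors. In the other direction stood Cd300c (-4.29 ± 0.40), Ly6c2 (-4.28 ± 0.59), Cd209d (-3.93 ± 0.53), Laptm4b (-3.39 ± 0.48), Irf8 (-3.36 ± 0.35) and Upk1b (-3.23 ± 0.39). Irf8 differed by 3.51 ± 0.24 between CD24 DC and CD172a DC and by 0.15 ± 0.26 between pre-CD8 and pre-CD4. Id2 differed more in the progenitors, by 4.67 ± 0.22 against 1.48 ± 0.20 in the mature cells, with a difference between stages of 3.19 ± 0.30 (adjusted p = 0.000143). The remaining panel genes, Batf3 (2.48 ± 0.61), Nfil3 (1.13 ± 0.57), Zbtb46 (-0.11 ± 0.34), Irf4 (0.84 ± 0.52), Klf4 (0.23 ± 0.58), Xcr1 (-2.12 ± 0.59) and Mki67 (0.35 ± 0.41), were not called. Batf3 was called without CD172a DC 1 (3.29, adjusted p = 0.0133), without the 5 arrays numbered 1 (0.043), with quantile normalization (0.0291), with array weights (0.0412) and with the interquartile range as a covariate (0.027). Xcr1 was called without pre-CD8 2 (-2.99, adjusted p = 0.00672) and with array weights (0.0274). Of the 26 lists, 12 were called, pDC markers also with an estimated correlation (median -1.08, adjusted p = 3.51e-05, and 0.0342 with an estimated correlation). The count was 130 without CD172a DC 1, 99 and 125 without pre-CD4 1 and 2, and 145 without pre-CD8 1, and without the 5 arrays numbered 1 there were 67 higher and 17 lower, against 118 and 111 over all arrays. Il1r2 lost its call without CD172a DC 2, pre-CD4 1, pre-CD4 2 or pre-CD8 1 (adjusted p = 0.0782, 0.063, 0.0803 and 0.0766). The other called lists were those of cDC1 (median -0.802, adjusted p = 0.00108, and 0.45 with an estimated correlation), cDC2 (0.574, 1.71e-05 and 0.168), shared cDC (0.0381, 0.0148 and 0.369) and progenitor (0.389, 0.0108 and 0.265) genes. Called too were those of MHC class I presentation (-0.404, 0.00186 and 0.278), interferon (0.624, 0.000953 and 0.372), Toll-like receptor (0.366, 0.00494 and 0.344) and oxidative phosphorylation (-0.553, 0.000111 and 0.439) genes. The last were those of stress (0.296, 0.00692 and 0.464), NK cell (0.593, 0.000457 and 0.226) and basophil (1.19, 3.93e-07 and 0.13) genes. On leaving out an array, calls were lost for the cDC1 list without pre-CD8 1 (0.137), the shared cDC list without CD172a DC 2, pre-CD4 1 or pre-CD8 2 (0.0563 to 0.168) and the progenitor list without pre-CD4 2 (0.0723). They were also lost for the interferon list without CD172a DC 2 (0.0517), the Toll-like receptor list without CD172a DC 2 or CD24 DC 3 (0.0569 to 0.0637) and the stress list without CD172a DC 2 (0.3). Between stages, calls ended without the 5 arrays numbered 1 for the cDC1 list (0.795), the MHC class I presentation list (0.46) and the oxidative phosphorylation list (0.0731) and with the interquartile covariate for the shared cDC list (0.0512) and the oxidative phosphorylation list (0.0505) (adjusted p in brackets). Calls failed too with quantile normalization for the MHC class I presentation list (0.0601) and with the filter on dim genes at the 40th percentile for the progenitor list (0.0583). They ended too with fry for the cDC1 list, the shared cDC list, the progenitor list, the MHC class I presentation list, the interferon list, the Toll-like receptor list, the oxidative phosphorylation list, the stress list and the NK cell list (0.0529 to 0.302).

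**Figure D4:**
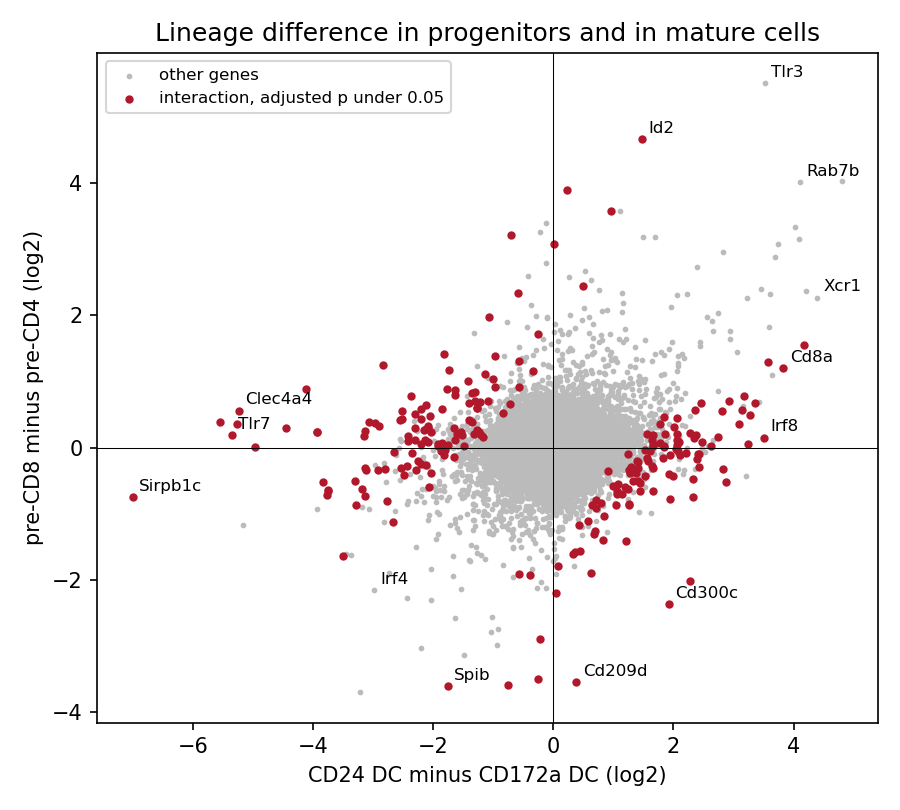
Log2 difference of each of 22184 genes between CD24 DC and CD172a DC (x axis) and between pre-CD8 and pre-CD4 (y axis), with the 229 genes of the stage test in red. Tlr3 and Rab7b lie high on both axes; Tlr7 (-5.36 and 0.19) and Irf8 (3.51 and 0.15) lie far out on the x axis alone.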

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

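The interaction contrast and the count over remaining probe sets were planned; the tests of explanations in this part were chosen only after the results were seen, with p-values of limma's fry adjusted over 5 such tests. The lineage difference itself differed between progenitor and mature stage for 229 genes, tested as an interaction. With a positive difference of progenitor minus mature stage stood Sirpb1c (6.26), Clec4a1 (5.94), Clec4a4 (5.79), Sirpb1a (5.63), Tlr7 (5.55) and Il1r2 (5.0), and in the other direction Cd300c (-4.29), Ly6c2 (-4.28), Cd209d (-3.93), Laptm4b (-3.39), Irf8 (-3.36) and Upk1b (-3.23). The pDC marker list had a median interaction of -1.08. Among 11620 probe sets outside the gene test, those past the threshold numbered 74 in pre-CD8 against CDP, 41 in pre-CD4 against CDP, 6 in pre-CD8 against pre-CD4, 251 in CD24 DC against CD172a DC, 97 in CD24 DC against pre-CD8 and 514 in CD172a DC against pre-CD4. No gene was named for these.

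Nr4a3, Nr4a1, Egr2 and Il1b were higher in both mature populations than in their progenitors. For monocytes or macrophages in the CD24 DC sort, their 17 markers had a median of 0.13 (SD 1.59 over markers) there, with 4 called higher and 3 lower. The 13 with a pre-CD8 mean under 7 had one of 0.582 (SD 1.16), and the largest rise of any marker was 2.21. The smallest change of the 4 genes was 4.0, a bound that replaced an earlier one (a median below 0 in both steps) after the medians were seen. These 4 genes were picked after their rises had been seen, and a marker's rise depends on its level in such cells. A low marker median therefore cannot exclude them, and this stays open. In CD172a DC the markers had a median of 0.611 (SD 2.75) against 4.13. The 12 of them with a pre-CD4 mean under 7 had a median of 1.26 (SD 1.2), more than 2 SD below 4.13, but 7 of the 17 were called higher and 3 lower, and over all of them the spread was too wide for the bound set, so this stays open. Induction during enzymatic digestion of the spleen, the deciding value for which was a median of 0.53 over 4 heat-shock genes in CD24 DC (0.774 in CD172a DC, fry's adjusted p = 0.569 and adjusted p = 0.316), cannot be told apart from maturation, since stage, tissue and digestion changed together. The stress list was also higher in pre-CD8 than in CDP, median 1.02 (adjusted p = 1.4e-06, and 0.214 with an estimated correlation), with both taken from marrow without enzymes, so a rise with maturation stays open too.

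Spib and Siglech were higher in pre-CD4 than in CDP and pre-CD8 arrays, and Upb1 higher than in CDP. The pre-CD4 gate did not exclude Siglec H, but it was low for CD117 and positive for CD115, whose gene Csf1r stood at 8.80 ± 0.04, which would remove mature pDCs. Pre-CD8 cells were sorted as Siglec H negative, so lower pDC markers in pre-CD8 can follow in part from its gate. The 14 pDC markers other than Spib and Upb1 had a median of 0.555 against CDP (fry's adjusted p = 0.00494) and 1.10 against pre-CD8 (adjusted p = 0.000141), with 11 of 14 means higher than in CDP. This is consistent with pDC precursors, or pDCs that passed the gate. Of the 14, 3 were called higher and 1, Dntt, lower than in CDP, and expression of these genes by the pre-CD4 progenitor itself, which shares that prediction, stays equally open.

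Prg2, Cpa3 and Ctsg were higher in pre-CD8 than in pre-CD4 arrays (Ctsg by 1.72 ± 0.33, a call lost without CDP 3, pre-CD4 2, pre-CD8 1 or pre-CD8 2, adjusted p from 0.0536 to 0.318). CDPs left in the sort are argued against for Prg2 and Cpa3, which stood 2.46 ± 0.57 and 1.77 ± 0.28 above their CDP level, though Prg2 lost its call without CDP 1, CDP 3 or pre-CD8 2 (1.17 without the latter, adjusted p = 0.271). For Ctsg the carry-over stays open: it kept 10.9% of its CDP level, and of 934 abundant CDP genes 5 lay below that share and 0 by more than 2 standard errors, though a plain fall of Ctsg gives the same. Basophils, mast cells or eosinophils in the pre-CD8 gate, which was positive for CD135 and CD11c and intermediate for MHC class II and would remove mature ones, could account for Prg2 and Cpa3, as the other 8 markers all had higher means, with a median of 0.795 (fry's adjusted p = 0.031) and 0 of them called. Prg2 read 6.35 and 8.91 on the pre-CD8 arrays, and the fry test was not repeated without either array. In the same comparison the neutrophil marker median was -0.262 without pre-CD8 2 and 2.89 without pre-CD8 1. A granulocyte signal on pre-CD8 2 was not tested apart, for Ctsg either, nor was a pre-CD8 progenitor that expresses these genes.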

How the results depend on the processing

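All alternatives were planned, except the interquartile covariate, the fit without the 5 arrays numbered 1 and the simulation with deviations shared by number, which were chosen after the results were seen. Counts are in the order of the report, from pre-CD8 against CDP to CD172a DC against pre-CD4 and then the contrast between stages. Leaving out any 1 array gave 510 to 1315, 298 to 1302, 58 to 194, 556 to 1461, 571 to 1940, 1233 to 3417 and 99 to 278 genes. A group left with 1 array was assumed to vary like the others. Treat against a 1.5-fold change gave 267, 198, 50, 308, 442, 802 and 73 genes, and without the 5 arrays numbered 1 there were 502, 427, 89, 508, 753, 996 and 84. Array weights gave 1629 and 2021 genes against CDP, 2349 for CD24 DC against CD172a DC, 2556 for CD24 DC against pre-CD8 and 481 between stages. With the interquartile covariate there were 1600 genes in pre-CD4 against CDP, 1336 in CD172a DC against pre-CD4 and 404 between stages. Fits of only the groups compared gave 34 genes for pre-CD8 against pre-CD4, 611 for CD24 DC against CD172a DC, 683 for CD24 DC against pre-CD8 and 134 between stages; fewer samples entered those fits. Under the remaining alternatives the counts stayed within 1.5 times, and the cause of these shifts was not tested. Background was not measured, so signal over background sets a limit that could not be given.

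Of 182 list tests 85 were called, 78 to 91 on leaving out an array, 16 with an estimated correlation, 57 with fry and 133 with its mixed test, which asks another question. The CD24 DC genes had a median of 0.105 to 0.28 between the progenitors on leaving out an array and lost their call with an estimated correlation (0.193, p = 0.0736). The CD172a DC genes had -0.214 to -0.128. Lists from an adjusted p under 0.01 and a 4-fold change gave 0.686 over 90 genes and -0.299 over 105. Their camera p with an estimated correlation was 0.00387 and 0.0236. Without the 5 arrays numbered 1 the medians of the 2-fold lists were 0.502 and -0.304. The smallest CD24 DC value, 0.105, came without pre-CD4 2. The direction of the list test turned for neutrophil markers in pre-CD8 against pre-CD4 without pre-CD8 2 (-0.262 to 2.89 on leaving out an array) and for oxidative phosphorylation in CD24 DC against pre-CD8 with the interquartile covariate (0.023). The correlation of both changes from CDP was 0.725, and in 100 simulations of unchanged groups 0.401, or 0.467 with deviations shared by number.

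With the replicate number as a block the counts were 1218, 1176, 182, 1443, 1319, 3528 and 292, 87 lists were called, and the medians of the CD24 DC and CD172a DC genes were 0.178 and -0.128. The block ended the calls of 3 lists in pre-CD4 against CDP, the cDC1 (adjusted p = 0.183), interferon-stimulated (0.0535) and cholesterol synthesis genes (0.0858). It brought in Klf4 in pre-CD8 against CDP (0.0347) and in CD24 DC against CD172a DC (0.0179), and the lists of megakaryocyte and platelet markers in pre-CD8 against CDP (0.042), cholesterol synthesis in CD24 DC against CD172a DC (0.0272) and cell cycle (0.0336), neutrophil (0.044) and erythroid genes (0.0336) between stages. It changed no other call of a named gene or list. CD172a DC arrays did not deviate with those of their number, so the block says less for their comparisons.

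Reversals among named genes were all in genes not called in the comparison: Mki67 in pre-CD8 against pre-CD4 (-0.378 to 0.0663 on leaving out an array), Nfil3 in CD24 DC against CD172a DC (0.0294 with the interquartile covariate, 0.0561 without the 5 arrays numbered 1, -0.604 to 0.29 on leaving out an array), Batf3 in CD24 DC against pre-CD8 (0.235 with the interquartile covariate, -0.424 to 0.101 on leaving out an array), Id2 in CD24 DC against pre-CD8 (0.0685 with the interquartile covariate). Further ones were Zbtb46 in CD24 DC against pre-CD8 (-0.141 with array weights), Klf4 in CD172a DC against pre-CD4 (0.182 without the 5 arrays numbered 1, -1.04 to 0.327 on leaving out an array), Zbtb46 in CD172a DC against pre-CD4 (-0.13 with median centring, -0.136 to 0.27 on leaving out an array). In the rest, these were Klf4 in the contrast between stages (-0.453 to 0.914 on leaving out an array), Mki67 in the contrast between stages (-0.0325 with array weights), Zbtb46 in the contrast between stages (0.208 with array weights, 0.313 without the 5 arrays numbered 1, -0.317 to 0.0897 on leaving out an array). The cause was not tested. Over all alternatives, the named gene results stayed on their side of the threshold with the same direction in 6260 cases, fell below it in 118 and rose past it in 21. Many of these genes were named for their large changes, and many settings left the compared arrays unchanged. Genes that stayed uncalled count as the same too, so these numbers do not measure robustness.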

Other observations

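The lists, their tests and the rule for named genes in this part were planned; no test here was chosen after the result was seen, apart from the interquartile covariate and the fit without the 5 arrays numbered 1. Against CDP, 5 of 21 trafficking receptor genes were higher and 2 lower in pre-CD8 (adjusted p = 0.0198, and 0.126 with an estimated correlation), and 3 and 1 in pre-CD4 (adjusted p = 0.0111, and 0.0981 with an estimated correlation). Itgb2, the beta chain of the leukocyte integrins, was 2.57 ± 0.23 higher in pre-CD8 and 2.40 ± 0.23 in pre-CD4, and Itgb7, a partner of integrin alpha 4, 1.94 ± 0.27 and 2.01 ± 0.27 higher. S1pr3, a receptor for sphingosine-1-phosphate, was lower (-2.52 ± 0.37 and -1.83 ± 0.37). Without pre-CD4 array 2 it was not called in pre-CD4 (-1.54, adjusted p = 0.162). With maturation Itgb7 fell, at -1.93 ± 0.27 in CD24 DC and -2.05 ± 0.30 in CD172a DC. Bcl6, a transcriptional repressor, was higher than in CDP in pre-CD8 (2.72 ± 0.20) and pre-CD4 (1.93 ± 0.20). The transcription factor list was called in both, with 9 of 37 higher in pre-CD8 (adjusted p = 2.25e-05, and 0.107 with an estimated correlation) and 9 in pre-CD4 (adjusted p = 2.85e-07, and 0.0681 with an estimated correlation). Runx3, a runt-domain factor, was 2.33 ± 0.35 higher in CD172a DC than in pre-CD4.

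Of the interferon-stimulated genes, the antiviral GTPase gene Mx1 was 2.23 ± 0.27 higher in pre-CD8 and 1.80 ± 0.27 in pre-CD4, and Irf7, a factor of interferon induction, 2.02 ± 0.30 and 1.86 ± 0.30, while Gbp3 was lower (-2.29 ± 0.30 and -1.59 ± 0.30, not called in pre-CD4 without pre-CD4 2, -1.41, adjusted p = 0.119). The list had 5 of 20 higher and 1 lower than CDP in pre-CD8 (adjusted p = 0.000251, and 0.344 with an estimated correlation) and 4 and 1 in pre-CD4 (adjusted p = 0.0111, and 0.492 with an estimated correlation). Without pre-CD8 array 2 its adjusted p was 0.0558 and without pre-CD4 array 2 0.189, and with the replicate number as a block the pre-CD4 call was lost (0.0535). Among Toll-like receptor genes, Tlr12 was 2.04 ± 0.27 higher in pre-CD8 and 1.84 ± 0.27 in pre-CD4 than in CDP, and 2.38 ± 0.27 higher in CD24 DC than in CD172a DC. Tissue-dissociation stress genes were higher in 9 and lower in 1 of 23 in pre-CD8 (adjusted p = 1.4e-06, and 0.214 with an estimated correlation) and in 4 and 1 in pre-CD4 (adjusted p = 7.97e-05, and 0.317 with an estimated correlation), although all marrow was prepared in the same way. Their largest members were the activation gene Cd69, which was lower (-3.15 ± 0.39 and -2.76 ± 0.39), and the signalling regulator Rgs1, which was higher (2.93 ± 0.43 and 2.00 ± 0.43). The pre-CD4 call of Rgs1 was lost without pre-CD4 2 (1.73, adjusted p = 0.192), pre-CD4 1 (0.0596) or CDP 2 (0.053). Cholesterol synthesis genes had medians of 0.53 in pre-CD8 (adjusted p = 0.000817, and 0.348 with an estimated correlation) and 0.39 in pre-CD4 against CDP (adjusted p = 0.0256, and 0.496 with an estimated correlation), a pre-CD4 call lost with the replicate block (adjusted p = 0.0858) and without CDP 2 (0.0957) or pre-CD4 1 (0.196). The median was -0.64 in CD172a DC against pre-CD4 (adjusted p = 0.00224, and 0.372 with an estimated correlation; with the interquartile covariate -0.326, not called, adjusted p = 0.464), where Fdps, a farnesyl diphosphate synthase, stood at -2.86 ± 0.42. Cell cycle genes had a median of -0.29 in pre-CD8 against pre-CD4 (adjusted p = 5.13e-05, and 0.496 with an estimated correlation), with no member called. Among these results, further calls against CDP were lost in pre-CD8 with the interquartile covariate for the trafficking list (0.0547) and with fry for the interferon list and the cholesterol synthesis list (0.0572 to 0.0764) (adjusted p in brackets). In pre-CD4 they were lost without the 5 arrays numbered 1 for Mx1 (0.0703), the trafficking list (0.0568) and the cholesterol synthesis list (0.277) and in the fit of only the groups compared for Rgs1 (0.0631). Calls were lost there too under treat for Gbp3, Irf7, Rgs1 and S1pr3 (0.0512 to 0.201) and with fry for the interferon list, the cholesterol synthesis list and the stress list (0.0689 to 0.233). With fry the cell cycle list (adjusted p = 0.414) and the cholesterol list of CD172a DC (0.0572) were not called.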
